A study of Mus musculus with 4 samples.

How the data were processed

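Liver RNA from male mice was measured on 1-colour Agilent mouse oligonucleotide arrays of the 44K type, labelled with Cy3. The 4 samples are 1 wild-type and 1 catalase knockout liver sample on a normal diet (18% of calories from fat) and 1 of each genotype on a high-fat diet (60.3% of calories from fat). The diets were given for 11 weeks, from 29 to 40 weeks of age, per the labels' protocols. There was 1 array per group. The labels do not say whether a sample came from 1 animal or from a pool.

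Per the file headers, the deposited scanner files hold spot intensity values from Feature Extraction 11.5.1.1, including a background-subtracted processed signal on a linear scale with an error from the scanner's error model. Values were extracted with GeneSpring GX 7.3 before the authors compared groups, per the series' design text. The scaling and the size or test that the authors used for that comparison are not given in the sources used here. The deposited value table of the whole series holds intensity on a linear scale with no centring. Its values lay within 1% of the scanner's mean processed signal for 99.7%, 99.7%, 99.7% and 99.7% of probes on the 4 arrays, and its column medians were 79.87, 75.87, 72.38 and 89.16 in the order wild type on normal diet, wild type on high-fat diet, knockout on normal diet and knockout on high-fat diet. Its scale was found from this comparison, and direction does not apply to 1-colour values. All 4 arrays lay on 1 slide in 1 scan, so neither could be fitted as a batch.

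Control spots were left out, and so were spots with an outlier flag unless every spot of the probe was flagged. Outside the 399 probes with 10 spots, a flagged spot was therefore kept. The arrays held 98 to 186 flagged spots, and the flag was not used when genes were counted as changed. The remaining spots of each probe were averaged as log2 of the processed signal, and each array's 75th percentile over 39429 probes was subtracted. The scanner files carry no gene symbols, so 27508 probes were named by matching their accession, without its version, to a RefSeq gene table of assembly GRCm38.p6. The other 11921 probes stayed unnamed. The table was used for names and gene order only. Of the 20886 genes named, 5512 had more than 1 probe, and each gene was represented by the probe with the highest mean log2 signal over the 4 arrays.

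Each comparison is the log2 difference between 2 arrays. A gene was counted as changed at 2-fold or more when its probe was well above background on both arrays by the scanner's own flag. Where it was well above background on only 1 array, the array without it was set to the higher of the lowest signal among probes well above background and the probe's own signal, and the gene was counted when that bound reached 2-fold. Such sizes are written as "at least N-fold". Where the probe's own signal was the higher, as for Cyp2b13 and Cyp2b9, the size is the measured ratio. Its scanner error, 0.40 and 0.44 on the log2 scale for these 2 genes between genotypes on normal diet, then leaves room for a smaller difference. The words rose, fell and changed are used only for genes that met this rule. It is a rule of size with no replicate check, so no p-value is given for any comparison of 2 arrays. The error after each ± is the scanner's error model for a difference. It covers spot measurement only, and not the spread between animals.

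The 35 gene lists, the size rule, the comparisons and the rule for named genes were fixed before the data were examined. That rule takes Cat first. It then takes, per comparison, the 10 largest increases and 10 largest decreases that stayed at 2-fold under 3 scalings and another background correction, the 2 largest bounds each way, and up to 4 members of each list with the largest absolute difference. Unnamed loci and clone names were left out. A few further list members were named after their values were seen. For genes changed in 2 comparisons the 10 largest each way were taken, and for the difference of diet effects the 5 largest each way. A list's median log2 difference was set against 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean signal. Its place among them describes these arrays and is not a test. The lists share some genes, so they are not independent of each other.

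An additive model of genotype and diet was fitted with limma 3.58.1 in R 4.3.3 on genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment at 0.05. Its 1 residual degree of freedom is the interaction of diet and genotype, so it takes that interaction as error. Other steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

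The size rule was tested on simulated data with 200 changed genes. For the diet comparison in wild type, over 13733 genes, it recovered 92% of genes changed 2.5-fold, 100% of those changed 4-fold and 4% of those changed 1.5-fold, with 0 false calls. For diet in the knockout and for genotype on high-fat diet it recovered 88% of genes changed 2.5-fold, with 2 false calls each. The simulated spread was drawn from a normal distribution, with the size seen between 2 arrays for most genes. It holds no single aberrant spots and no calls that rest on a bound, so few false calls followed from that setting. In simulated data for the diet term over 14346 genes, the additive fit recovered 68 of 100 genes changed by 2 on the log2 scale and 94 of 100 changed by 4, with 14 false calls. These changes were the same in both genotypes, and the noise was set close to the prior variance of the real fit. The simulation therefore does not show what the fit can recover where the diet effect differs between genotypes. Of 200 random lists of 25 genes, 2.5% fell outside the central 95% in a simulation over 13733 genes.

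The alternatives were scaling to the median, quantile and cyclic loess normalization, normexp background correction with an offset of 50, the deposited value table, the mean of all probes of a gene, other filters on dim probes, thresholds of 1.5-fold and 3-fold, a change of over 3 scanner errors, and a variance trend in the additive fit. The scanner files used here lack a mean foreground column, so normexp used the median foreground signal in its place. Leaving out replicates was not possible with 1 array per group, and a slide block did not apply.

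Between 60.3% and 63.9% of probes were well above background on each array. The number of arrays limits the precision.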

Results

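The data are liver expression profiles from a design that crosses genotype with diet. Male mice were wild type or lacked catalase, the peroxisomal enzyme that breaks down hydrogen peroxide, and ate a normal or a high-fat diet for 11 weeks. There were 4 arrays, 1 for each group, so no value below has a replicate. Of 39429 probes, 24580 were well above background on the wild-type normal-diet array, 23757 on the wild-type high-fat array, 23997 on the knockout normal-diet array and 25184 on the knockout high-fat array. The 75th percentile of the processed signal was 1080, 1090, 1077 and 1229 in that order. No spot was saturated. The scanner error of a typical difference between 2 arrays was 0.20 on the log2 scale.

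Cat itself was read by 2 probes. The brighter probe had a scaled log2 signal of 4.89 in wild type on normal diet, 4.75 in wild type on high-fat diet, 1.13 in the knockout on normal diet and 0.95 in the knockout on high-fat diet. The knockout was therefore lower by 13.5-fold on normal diet and by 14.0-fold on high-fat diet, with log2 differences of -3.76 ± 0.20 and -3.81 ± 0.20. On the other probe the differences were -4.17 and -4.39. Both probes stayed well above background in the knockout. The labels do not say whether they lie in the deleted part of the gene, so the low values match the labels but do not measure how much intact transcript remained. Diet moved Cat by -0.14 ± 0.20 in wild type and by -0.19 ± 0.20 in the knockout.

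**Figure D1:**
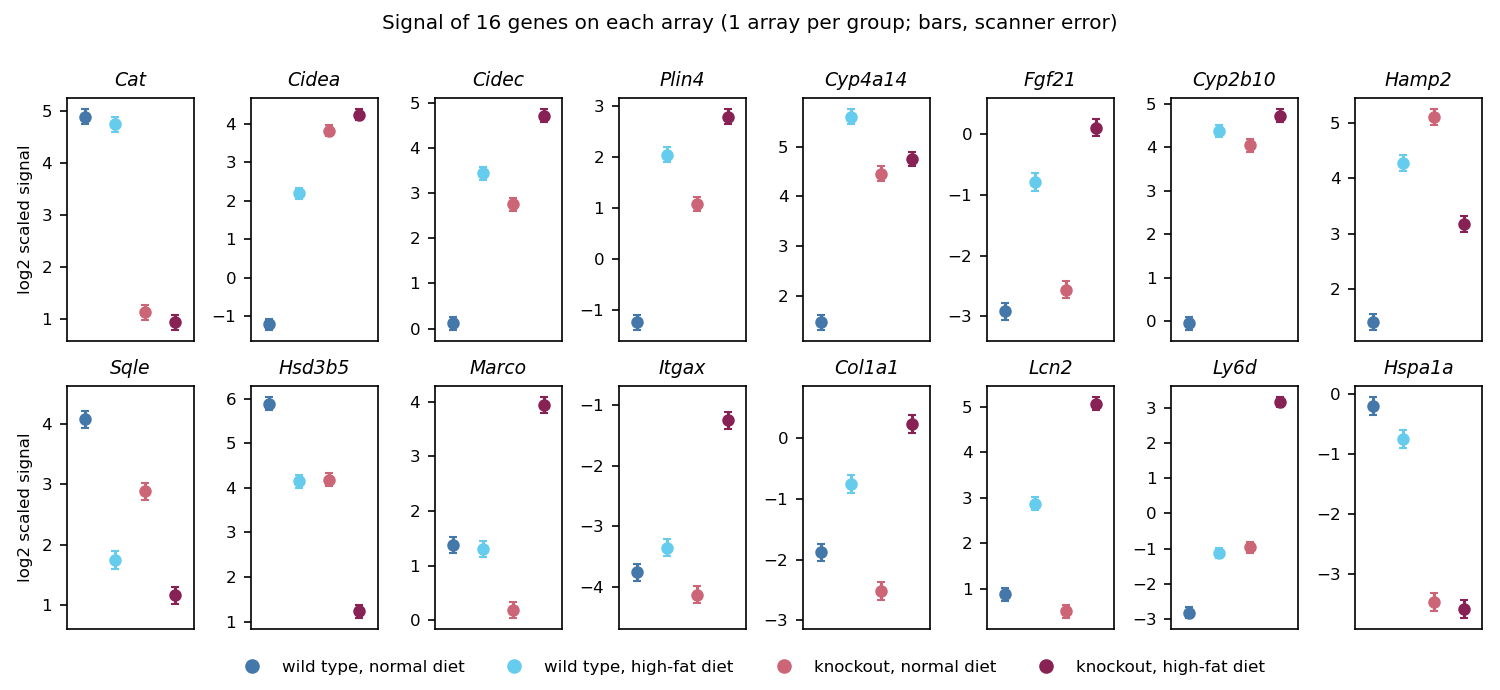
Scaled log2 signal of 16 genes on the 4 arrays, with 1 point per array and bars for the median scanner error of an array. Cat was low on both knockout arrays, Cidea and Cyp2b10 were low on the wild-type normal-diet array alone, and Marco and Lcn2 were highest on the knockout high-fat array.

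The first comparison asks what the high-fat diet did in wild-type liver. Of 24 measured lipid droplet and steatosis genes, 9 rose and 0 fell, with a median log2 difference of 0.60. Cidea rose by 3.40 ± 0.20 on the log2 scale, Cidec by 3.32 ± 0.20 and Plin4 by 3.27 ± 0.20, and these encode proteins that coat or fuse droplets. Vldlr, a receptor for triglyceride-rich lipoproteins, rose by 2.71 ± 0.22. Of 25 cholesterol synthesis and uptake genes, 15 fell and 0 rose, with a median of -1.06. Sqle, which encodes squalene epoxidase, fell by 2.32 ± 0.20 and Idi1 by 1.60 ± 0.20.

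Among 26 genes induced by the fatty acid receptor PPARalpha, 8 rose and 0 fell, with a median of 0.55. Cyp4a14, a fatty acid hydroxylase, rose by 4.13 ± 0.20, Fgf21, a secreted hormone of fasting, by 2.13 ± 0.21, and Cd36, a fatty acid transporter, by 1.85 ± 0.20. The 23 genes of mitochondrial fatty acid oxidation and ketogenesis had a median of 0.30, and 1 of them rose, the thioesterase gene Acot2, by 1.47 ± 0.24. Of 40 peroxisomal oxidation genes measured on both arrays, with a median of 0.03, Acot3 rose by 2.43 ± 0.21 and Acot4 by 1.15 ± 0.20. Abcd2, a peroxisomal transporter gene that was not well above background on the normal-diet array, was at least 5.8-fold higher. In de novo lipogenesis 2 genes fell, Acss2 by 1.37 ± 0.20 and Elovl3 by 1.22 ± 0.20, and the median over 28 genes was -0.19.

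Genes whose liver expression differs between the sexes moved in opposite directions by list. Of the female-biased genes 12 rose and 2 fell, with a median of 0.98 over the 16 measured on both arrays. Of 22 male-biased genes 10 fell and 0 rose, with a median of -0.94. Cyp2b13 and Cyp2b9 were not well above background on the normal-diet array and were at least 78.1-fold and at least 52.6-fold higher on the high-fat array. Slc22a27, an organic anion transporter gene, rose by 3.54 ± 0.21, and Hamp2, a relative of the iron hormone hepcidin, by 2.86 ± 0.20. Moxd1 fell by 5.15 ± 0.23, Cyp4a12a by 1.98 ± 0.20 and Hsd3b5, a steroid dehydrogenase gene, by 1.74 ± 0.20. In the xenobiotic list 4 genes rose and 4 fell, with Cyp2b10 up by 4.42 ± 0.20 and Cyp3a11 down by 1.68 ± 0.20.

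Macrophage markers had a median of 0.30 in this comparison, with 21 of 24 values positive, and 0 rose or fell by 2-fold. Of the matrix genes 2 rose and 1 fell, with a median of 0.14 and Col1a1 up by 1.13 ± 0.21, and of the acute phase genes 3 rose and 0 fell, with Lcn2 up by 2.00 ± 0.20. Of the immediate early and heat shock genes 4 fell and 0 rose, with a median of -0.15, among them Junb by 1.34 ± 0.22 and Egr1 by 1.03 ± 0.20. Of the circadian genes 3 rose and 1 fell, with a median of 0.47, Ciart up by 1.61 ± 0.21 and Nr1d1 down by 1.14 ± 0.20. Syt10 rose by 4.61 ± 0.21 and Dnm1 by 3.97 ± 0.22, but the other Dnm1 probe differed by -0.20. Asns, the asparagine synthetase gene, fell by 2.44 ± 0.21, Fabp5 by 2.67 ± 0.20, Slc13a2 by 2.54 ± 0.24 and Csad, a taurine synthesis gene, by 2.35 ± 0.20. Of a list of pancreas, muscle, adipose and erythroid genes, kept for tissue carried over with liver, 2 rose and 0 fell, with a median of -0.30 over 9. These were the adipokine gene Cfd by 2.81 ± 0.20 and the haemoglobin gene Hba-a1 by 1.38 ± 0.20. In all, 261 genes rose and 338 fell, of which 105 and 153 rest on a bound, but 304 rose and 280 fell under median scaling and 293 and 294 with quantile normalization, so the excess of decreases depended on the scaling. Of the 51 changed genes with a further probe measured on both arrays, that probe also changed 2-fold the same way for 31.

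The same diet comparison was made in knockout liver. Of the macrophage and Kupffer cell markers 18 rose and 0 fell, and the median over 24 measured genes was 1.32. Marco, a scavenger receptor, rose by 3.74 ± 0.20, Itgax, which encodes an integrin of lipid-laden macrophages and dendritic cells, by 2.87 ± 0.25, Trem2, a lipid-sensing receptor, by 2.35 ± 0.21 and Adgre1, the F4/80 antigen, by 1.98 ± 0.20. Of the stellate cell and matrix genes 11 rose and 0 fell, with a median of 0.78. The collagen genes Col1a1, Col3a1 and Col1a2 rose by 2.75 ± 0.21, 2.13 ± 0.20 and 1.94 ± 0.20. Timp1, an inhibitor of matrix proteases, was at least 16.1-fold higher. Over the same arrays the endothelial markers had a median of 0.08, above the -0.08 of matched random lists. The endothelial median became -0.02 under median scaling, a setting that moved every gene by -0.11 and so left that distance as it was. The hepatocyte identity genes had a median of -0.29, close to the -0.23 of random lists of equally bright genes.

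Of the cytokine and adhesion genes 8 rose and 0 fell, among them the chemokine genes Ccl4 by 2.53 ± 0.29 and Ccl2 by 2.36 ± 0.07. Of 27 acute phase genes 6 rose and 0 fell, with Lcn2, a siderophore-binding protein gene, up by 4.57 ± 0.20, Saa1 by 2.52 ± 0.20 and Orm3 by 1.85 ± 0.20. Of the neutrophil markers 5 rose and 1 fell, with S100a8 up by 2.49 ± 0.21 and S100a9 by 2.45 ± 0.20, and the median of 0.36 had a bootstrap interval over genes of -0.18 to 2.07. Of the interferon-response genes 5 rose and 0 fell, including Ifi44 by 1.41 ± 0.21 and Oas2 by 1.17 ± 0.21. Of the proliferation genes 8 rose and 0 fell, including Prc1 by 1.63 ± 0.24 and Mki67 by 1.60 ± 0.21. In the lymphocyte list 5 genes rose and 1 fell, and the median was -0.01, with 9 positive and 11 negative values. The risers included H2-Aa by 1.36 ± 0.20 and Ptprc by 1.22 ± 0.22, which other leukocytes also express, and the plasma cell gene Jchain fell by 1.72 ± 0.21.

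In the xenobiotic list of this comparison 12 genes fell and 2 rose, with a median of -0.59. Cyp2c55 fell by 2.49 ± 0.21, Cyp1a2 by 2.17 ± 0.20 and Cyp3a11 by 1.54 ± 0.20. Of 25 cholesterol genes 10 fell and 0 rose, with a median of -0.88, and Sqle fell by 1.72 ± 0.20. Of the male-biased genes 7 fell and 0 rose, including Hsd3b5 by 2.95 ± 0.20 and Slco1a1, a bile acid and steroid transporter gene, by 2.49 ± 0.20. Of the female-biased genes 4 rose and 2 fell, with a median of 0.20. Of 24 bile acid genes 3 fell, with a median of -0.34 against -0.15 for matched random lists, and of 17 periportal genes 3 fell, with a median of -0.47 against -0.19, among them Etnppl by 1.68 ± 0.20. After cyclic loess normalization 8 xenobiotic, 7 cholesterol, 6 male-biased, 1 bile acid and 1 periportal gene fell. Lipid droplet genes rose here too, 6 of 24, with Apoa4 up by 2.39 ± 0.20, Lpl by 2.16 ± 0.21 and Cidec by 1.96 ± 0.20. PPARalpha targets had a median of 0.14, and 3 of 26 rose, with Fgf21 up by 2.67 ± 0.21, whereas Cyp4a14 differed by 0.29 ± 0.20. The median of mitochondrial fatty acid oxidation genes was -0.01, above the -0.19 of matched random lists, and was 0.18 after quantile normalization. Hamp and Hamp2, the hepcidin genes, fell by 1.35 ± 0.20 and 1.92 ± 0.20.

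In the knockout 629 genes rose and 245 fell on the high-fat diet, of which 151 and 92 rest on a bound. Scaling to the median gave 510 and 323. That scaling moved the median of all measured genes by -0.11 in this comparison and by 0.14 between genotypes on normal diet. Further probes changed 2-fold the same way for 62 of 106 changed genes. Outside the lists, Ly6d rose by 4.12 ± 0.20, Ubd, a ubiquitin-like modifier gene, by 3.63 ± 0.22 and Sprr1a by 3.30 ± 0.21. Serpinb1a fell by 2.55 ± 0.20. In the list kept for carried-over tissue 2 genes rose and 0 fell, with a median of -0.25, namely Cfd by 3.59 ± 0.20 and the elastase gene Cela1 by 1.76 ± 0.23.

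**Figure D2:**
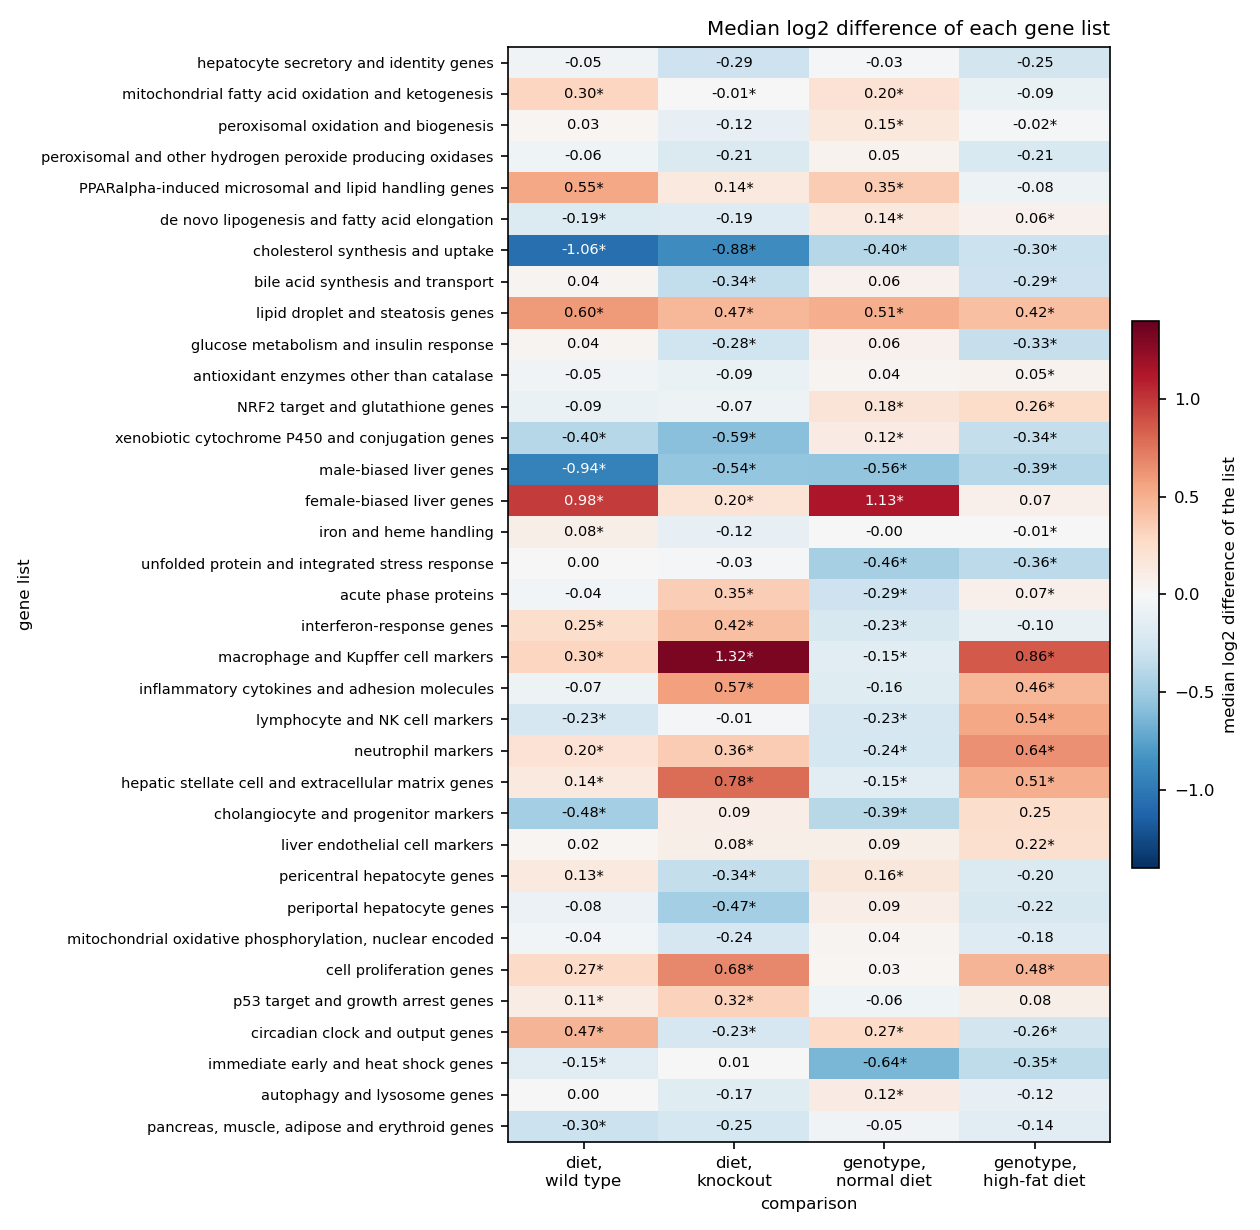
Median log2 difference of the 35 gene lists in the 4 comparisons, as colour and as printed value, over genes well above background on both arrays, with an asterisk where the median lay outside the central 95% of random lists matched on signal. Of 140 values 86 lay outside, against 7.0 for random lists, so an asterisk alone does not set a list apart from the others. Macrophage markers had the highest value, 1.32, for diet in the knockout, and cholesterol synthesis genes the lowest, -1.06, for diet in wild type.

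The third comparison sets knockout against wild type on the normal diet. Of the lipid droplet genes 7 rose and 1 fell, with a median of 0.51 over 24. Cidea rose by 5.03 ± 0.20, Cidec by 2.63 ± 0.20, Vldlr by 2.37 ± 0.22 and Plin4 by 2.31 ± 0.20, while Lpl fell by 1.27 ± 0.21. Of the female-biased genes 12 rose and 0 fell, with a median of 1.13 over 15 measured on both arrays. Hamp2 rose by 3.68 ± 0.20 and Slc22a27 by 2.49 ± 0.21. Cyp2b13 was at least 50.01-fold and Cyp2b9 at least 41.0-fold higher. Cyp2b10 rose by 4.09 ± 0.20.

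Of the male-biased genes 7 fell and 0 rose, with a median of -0.56. Moxd1 was at least 127.1-fold lower, Hsd3b5 fell by 1.70 ± 0.20 and Socs2, a regulator of growth hormone signalling, by 1.68 ± 0.06. Of 26 PPARalpha targets 6 rose and 0 fell, with a median of 0.35. Cyp4a14 rose by 2.98 ± 0.20 and Cyp4a10 by 1.35 ± 0.20, whereas Fgf21 differed by 0.36. In the NRF2 and glutathione list 2 of 34 rose, with a median of 0.18. These were Nqo1, a quinone reductase gene, by 1.17 ± 0.21 and Gsta2 by 1.15 ± 0.20. The 29 antioxidant enzymes other than catalase had a median of 0.04, and 0 rose or fell. The 40 peroxisomal oxidation genes had a median of 0.15, and 2 of the list rose, Acot3 by 1.98 ± 0.21 and Abcd2 by a bound. Hydrogen peroxide producing oxidases had a median of 0.05, and Hao2 was at least 5.9-fold higher.

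Of the immediate early and heat shock genes 6 fell and 0 rose, with a median of -0.64. Hspa1a, an inducible heat shock protein gene, fell by 3.27 ± 0.23, Egr1 by 2.31 ± 0.20 and Fos by 1.58 ± 0.07. The unfolded protein and stress response list had a median of -0.46, and 3 of 30 fell. Atf3 fell by 1.404 ± 0.25, Asns by 1.22 ± 0.20 and Creld2 by 1.16 ± 0.07. Of 27 acute phase genes 4 fell and 0 rose, with the metallothionein genes Mt2 and Mt1 down by 1.82 ± 0.20 and 1.21 ± 0.20. The chemokine genes Cxcl1 and Ccl2 fell by 2.77 ± 0.20 and 2.22 ± 0.07. Igfbp1, an insulin-repressed secreted protein gene, fell by 2.42 ± 0.20. Of 25 cholesterol genes 2 fell, among them Sqle by 1.19 ± 0.20.

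In all, 206 genes rose and 368 fell in the knockout on normal diet, of which 92 and 166 rest on a bound, and scaling to the median gave 264 and 285. Further probes changed 2-fold the same way for 20 of 44 changed genes. Other large changes were Tff3, a mucosal trefoil factor gene, down by 3.20 ± 0.22, Jmjd7 down by 3.01 ± 0.25 and Cd200r1, an inhibitory receptor of myeloid cells, up by 3.00 ± 0.31. This comparison and the diet comparison in wild type share the wild-type normal-diet array, so a value particular to that array enters both. Egr1, Junb, Cxcl1, Igfbp1 and Asns fell in both.

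The fourth comparison sets knockout against wild type on the high-fat diet. Macrophage markers were again higher, with 9 up and 0 down and a median of 0.86 over 24. Marco rose by 2.63 ± 0.20, Itgax by 2.10 ± 0.22, Trem2 by 1.52 ± 0.21 and Adgre1 by 1.46 ± 0.20. Of the matrix genes 5 rose and 0 fell, with a median of 0.51 and Timp1 up by 2.06 ± 0.22. Of the cytokine and adhesion genes 5 rose and 0 fell, including Ccl4 by 1.63 ± 0.24. Of the neutrophil markers 5 rose and 0 fell. This comparison shares the knockout high-fat array with the diet comparison in the knockout. Endothelial markers had a median of 0.22 against -0.05 for matched random lists. Lymphocyte markers had a median of 0.54 against -0.01, with 2 up and 1 down. Of 25 hepatocyte identity genes 1 fell and all values were negative, with a median of -0.25 against -0.19 for matched random lists. Of the cholangiocyte markers 2 rose and 0 fell, Spp1 by 1.78 ± 0.20 and Tspan8 by 1.33 ± 0.32. In the list kept for carried-over tissue Cela1 rose by 1.98 ± 0.24 and Hba-a1 fell by 1.478 ± 0.20.

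Of 24 bile acid genes 5 fell and 0 rose, including Slco1a1 by 2.43 ± 0.20 and Abcb11, the bile salt export pump, by 1.07 ± 0.20. After cyclic loess normalization 3 fell. Of the male-biased genes 6 fell, or 4 after cyclic loess normalization, with Hsd3b5 down by 2.91 ± 0.20. Of the female-biased genes 0 rose and 3 fell, with a median of 0.07 and Nipal1 down by 1.46 ± 0.21. Of the lipid droplet genes 4 rose and 0 fell, with a median of 0.42, Cidea up by 2.04 ± 0.20 and Lipe, the hormone-sensitive lipase gene, by 1.64 ± 0.25. The NRF2 list had a median of 0.26, and 1 of 34 rose, the carbonyl reductase gene Cbr3, by 3.07 ± 0.20. Antioxidant enzymes had a median of 0.05, which was -0.01 under median scaling, a setting that moved every gene here by -0.06. Of these 29 enzymes 0 rose or fell. Among early and heat shock genes Hspa1a fell by 2.84 ± 0.22 and Egr1 by 1.76 ± 0.20. Glucose metabolism genes had a median of -0.33 against -0.14 for matched random lists, and 3 of 25 fell, among them Pfkfb3 by 1.47 ± 0.20 and Tat by 1.07 ± 0.20.

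In all, 373 genes rose and 236 fell, of which 121 and 91 rest on a bound, and further probes changed 2-fold the same way for 25 of 57 changed genes. Outside the lists, Ly6d rose by 4.27 ± 0.20, Plcd3, a phospholipase gene, by 2.81 ± 0.25 and Cxcl13, a B cell chemokine gene, by 2.35 ± 0.25. Syt10 fell by 4.82 ± 0.21, Bst1 by 2.98 ± 0.26 and Map1a by 3.53 ± 0.29. Dnm1 fell by 4.12 ± 0.21, with -0.07 on its other probe.

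The diet effects in the 2 genotypes, which share no array, were then set side by side. In both, 65 genes rose and 55 fell, against 11.55 and 5.83 for independent lists. Another 17 changed in opposite directions, for which no such number was computed. The shared increases included Apoa4 by 2.31 and 2.39 in wild type and knockout, Fgf21 by 2.13 and 2.67, and Cidec by 3.32 and 1.96. Cfd, of the list kept for carried-over tissue, rose by 2.81 and 3.59. The cell cycle inhibitor gene Cdkn1a rose by 2.06 and 1.95 on its brighter probe, but the wild-type value was -1.53 with the mean of all its probes. Shared decreases included Slc13a2 by 2.54 and 2.90, Cyp4a12a by 1.98 and 1.96, Cyp3a16 by 1.91 and 1.95, and Sqle by 2.32 and 1.72. Across 13550 genes Pearson's r of the differences was 0.36 and Spearman's rho 0.33, and genes are not independent replicates.

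The genotype effects on the 2 diets overlapped less in number. On both diets 27 genes rose and 48 fell, Cat among them, against 5.40 and 6.11 for independent lists, and 29 changed in opposite directions. No number for independent lists was computed for opposite directions. The shared genes alone therefore do not show that the genotype effect was alike on both diets. Among those that rose on both were Cidea by 5.03 and 2.04, Plcd3 by 2.06 and 2.81, and Ly6d by 1.85 and 4.27 on normal and high-fat diet. Among those that fell were Hspa1a by 3.27 and 2.84, Jmjd7 by 3.01 and 2.67, Tmem254a by 1.79 and 2.47, Egr1 by 2.31 and 1.76, and Gadd45g, a growth arrest gene, by 1.63 and 2.13. Across 13550 genes r was 0.19 and rho 0.15.

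**Figure D3:**
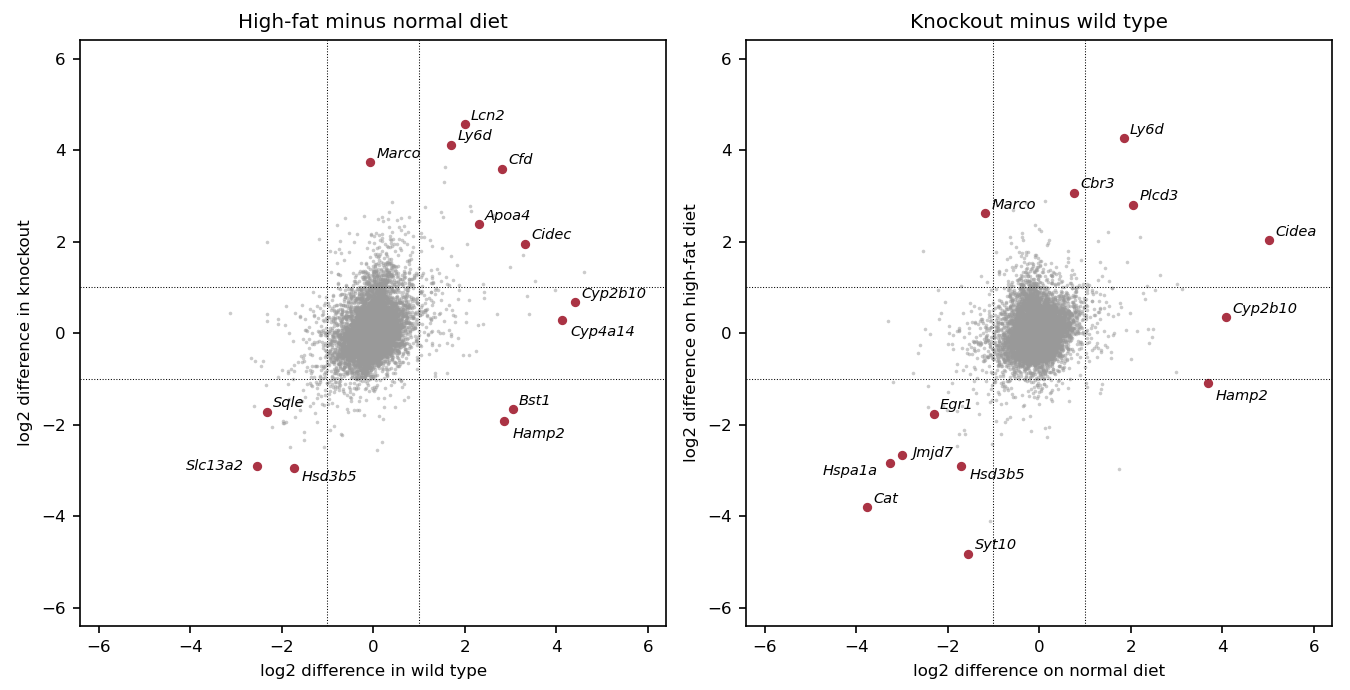
Log2 differences of 13550 genes well above background on all 4 arrays, for high-fat minus normal diet in wild type (x axis) and knockout (y axis), and for knockout minus wild type on normal (x axis) and high-fat diet (y axis), with dotted lines at 2-fold. Hamp2 lies far to the right and below 0 in both plots, at 2.86 and -1.92 for diet and at 3.68 and -1.10 for genotype.

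The diet effect differed 4-fold or more between genotypes for 71 genes, with 47 greater and 24 lower in the knockout, or 33 and 30 under median scaling. The difference could not be tested with 1 array per group. Hamp2, Bst1, Cyp4a14, Cyp2b10 and Syt10 had the most negative differences, at -4.79, -4.72, -3.84, -3.73 and -3.27. For Cyp4a14 and Cyp2b10 the knockout was already high on normal diet, with log2 signals of 4.46 and 4.05 against 1.47 and -0.04 in wild type. Xlr4a, Marco, Syt9, Nrg1 and Ccl2 had the most positive differences, at 4.32, 3.81, 3.58, 3.25 and 3.15.

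The additive limma fit called 0 of 14346 genes for diet and 0 for genotype at an adjusted p of 0.05, with 1425 and 1041 genes below 0.05 before adjustment. For Cat the genotype term was -3.78 ± 0.12 (SE), with an adjusted p of 0.289 in limma. With a variance trend limma called 1 gene for genotype, Cat, and with median scaling it called 377 genes for diet and 219 for genotype. In that median-scaled fit limma estimated an infinite number of prior degrees of freedom, so 1 common variance was used for every gene, against 2.17 prior degrees of freedom in the fit above.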

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

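The tests of a lower hepatocyte share in the first pattern, and of faulty spots and a shared control in the second, were chosen only after the results they bear on were seen.

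Several effects had opposite signs in the 2 groups in which they were measured, which is what drew attention to them, and with 1 array per group none of these differences was tested. On the high-fat diet the median of pericentral hepatocyte genes differed by 0.13 in wild type and by -0.34 in the knockout, and that of circadian genes by 0.47 and -0.23. Bst1, which encodes an ectoenzyme that cleaves NAD, differed by 3.05 and -1.67, and Hamp2 by 2.86 and -1.92. For knockout minus wild type, with the normal diet first and the high-fat diet second, the medians were 0.12 and -0.34 for xenobiotic genes, -0.29 and 0.0703 for acute phase genes, and 0.27 and -0.26 for circadian genes. They were -0.15 and 0.86 for macrophage markers, -0.23 and 0.54 for lymphocyte markers, and -0.15 and 0.51 for matrix genes. Those of neutrophil markers were -0.24 and 0.64, with bootstrap intervals over genes of -0.89 to 0.23 and -0.04 to 1.22, which both include 0. Median scaling moved every difference for genotype on normal diet by 0.14, about the size of the negative macrophage and matrix medians there. Their distance from 0 thus depends on the scaling, although neither median reversed under an alternative. Before that shift 23 of 24 macrophage and 26 of 31 matrix values were negative. Matched random lists had medians of 0.01 and -0.03, and a shift of every gene alike leaves the place of both lists below them as it was. Single genes in the same order were Bst1 at 1.73 and -2.98, Ciart at 1.37 and -1.11, Hamp2 at 3.68 and -1.10, Lpl at -1.27 and 1.25, and Marco at -1.18 and 2.63.

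The first pattern weighed is the higher macrophage, matrix and cytokine expression on the knockout high-fat array than on the knockout normal-diet array. A lower share of hepatocytes would raise the markers of other cell types alike. Endothelial markers had a median of 0.0825 (95% bootstrap interval over genes 0.03 to 0.38) against 1.32 for macrophage markers (1.07 to 1.55). Lymphocyte and cholangiocyte markers had medians of -0.01 (-0.17 to 0.57) and 0.09 (-0.09 to 0.61). For the knockout high-fat array against the wild-type high-fat array, endothelial, lymphocyte and cholangiocyte medians were 0.22, 0.54 and 0.25, with 0.86 for macrophages. A lower share is thus argued against as the sole source, but not as a part of it. The scaling of the knockout high-fat array is argued against by a macrophage median of 1.402 after cyclic loess normalization, against 0.0051 for matched random lists. Faulty spots are argued against by further probes with a median of 1.03 (0.97 to 1.99), although only 4 of the 33 genes had one. With diet in wild type the macrophage median was 0.30 (0.16 to 0.37), so a response to the diet that is larger without catalase, one that needs its lack, or a state particular to the animal or animals on 1 array could give these values, and none of these was tested.

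The second pattern is the higher female-biased and steatosis expression, and lower male-biased expression, on the wild-type high-fat and knockout normal-diet arrays than on the wild-type normal-diet array. Female animals are argued against, because 3 of 4 Y-linked genes (Ddx3y, Eif2s3y and Uty) were well above background on every array and Xist on 0, with a range of 0.28, and faulty spots by a median of 1.70 (1.64 to 2.57) for the further probes of 7 of the 31 genes. The knockout high-fat array also differed from the wild-type normal-diet array by a median of 2.18 (1.77 to 2.83) over 30 of these genes, against 0.73 from the knockout normal-diet array and 0.53 from the wild-type high-fat array. These genes were picked by their difference from the wild-type normal-diet array, so the values follow in part from that choice. A wild-type normal-diet array that stands apart cannot be told apart from effects of diet and genotype that do not add up, because 1 array serves as control for both. In the 2 comparisons that use that array, 74 genes rose and 209 fell in both, against 3.71 and 8.59 for independent lists. Of those measured on all 4 arrays 53 rose and 67 fell, against 51.2 and 52.0 in simulations of a shared control with no effects. The simulated spread was taken from the interaction of the genes measured on all 4 arrays, these genes included, and it holds real effects too. The simulation therefore cannot say how many of the shared changes come from the shared control, although many may.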

How the results depend on the processing

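The requirement that a further probe also change 2-fold was chosen only after seeing the data, and left 31, 62, 20 and 25 genes for diet in wild type, diet in the knockout, genotype on normal diet and genotype on high-fat diet, of the 51, 106, 44 and 57 changed genes with one. In the same order, normexp background gave 273, 409, 245 and 263 changed genes, no filter on dim probes 1551, 1795, 1611 and 1396, the 1.5-fold threshold 1604, 2266, 1549 and 1737, and the 3-fold threshold 249, 287, 235 and 201. Requiring a probe well above background on all 4 arrays leaves out every bound and gave 324 for diet in wild type and 288 and 353 for genotype on normal and high-fat diet. Genes changed the same way by diet in both genotypes numbered 69 with normexp and 300 with no filter, by genotype on both diets 39 and 231, and genes with differing diet effects 27 and 797. Lower thresholds and filters admit more genes by construction, and for normexp the cause was not tested. The additive fit called 377 genes for diet and 219 for genotype under median scaling, and 1 for genotype with a variance trend. The counts of all 9 results stayed within 1.5 times under quantile and cyclic loess normalization, the mean of all probes and the deposited value table. Of the values of named genes under the alternatives, 3873 of 4168 stayed within their error, 293 moved further and 2 reversed. Of those that stayed, 562 came from the filter on all 4 arrays and 601 from the deposited value table. The filter reuses the same differences and the table holds nearly the same signal, so these could hardly move. Normexp moved 178 and left 423. The reversed values were Cdkn1a at -1.53 and Prom1 at 2.25 for diet in wild type with the mean of all probes, since the other probe of each was well above background on only 1 of the 4 arrays. Of 1120 list medians under the alternatives 749 stayed within the spread of random lists, 361 moved further and 10 reversed. Median scaling gave 122 of those that moved, and it shifts every difference in a comparison by 1 constant. The cause of the other moves was not tested. The reversed medians for mitochondrial fatty acid oxidation with diet in the knockout were 0.18 (quantile), 0.16 (cyclic loess), 0.018 (normexp) and 0.0069 (mean of all probes). For genotype on high-fat diet they were 0.0776 and 0.0854 for peroxisomal oxidation and 0.0607 and 0.0656 for iron handling (quantile and cyclic loess), and -0.0116 for antioxidant enzymes (median scaling). For endothelial markers with diet in the knockout the value was -0.0227 (median scaling). Median scaling moves every gene of a comparison alike, by -0.11 for diet in the knockout and -0.06 for genotype on high-fat diet. The 2 reversals under it therefore leave the place of a list among other genes as it was. Leaving out replicates and a slide block did not apply, with 1 array per group on 1 slide. The signal over background limits the dim genes most, and between 60.3% and 63.9% of probes on each array were well above it.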

Other observations

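The count near Cat without Jmjd7 was chosen only after the result was seen, and the search near Cat itself was prompted by seeing Jmjd7 among the changed genes.

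Of 34 nuclear-encoded genes of oxidative phosphorylation, 0 reached 2-fold in any comparison. For diet in the knockout all 34 values were nonetheless negative, as were 32 for genotype on high-fat diet. The list was near its matched random lists, with medians of -0.04 and -0.24 for diet in wild type and knockout, where random lists of equally bright genes had -0.07 and -0.23. Of 25 autophagy and lysosome genes 0 reached 2-fold either. Among antioxidant enzymes other than catalase 1 gene rose in any comparison, Gpx3, a secreted glutathione peroxidase gene, by 1.07 on the high-fat diet in the knockout.

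Among probes that could not be matched to a named gene, 57 rose and 83 fell with diet in wild type, of 5389 measured on both arrays. The counts were 83 and 87 of 5522 for diet in the knockout, 59 and 118 of 5431 for genotype on normal diet, and 59 and 86 of 5462 for genotype on high-fat diet.

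The third pattern weighed is the set of 74 genes besides Cat that changed the same way in the knockout on both diets. Of these, 9 lay among the 200 protein-coding genes on either side of Cat, against 0.994 expected, and without Jmjd7, which prompted the search, 8 of 73 did, against 0.992 expected and at most 6 in 10000 random sets of measured genes. They were Cd59b (-1.36 on normal and -1.54 on high-fat diet), Bmf (-1.07 and -1.50), Chst14 (1.29 and 2.01), Exd1 (1.53 and 1.14), Itpka (1.097 and 1.04), Jmjd7 (-3.01 and -2.67), Disp2, Capn3 and Golm2, all on the same side of Cat. Only Cd59b was close, 7 genes away, and the others lay 113 to 198 genes away with none of the set between. DNA from another mouse strain carried along with the targeted gene is a hypothesis in line with the count, which needs genotypes of the animals, and a variant under a probe could also give such values, while faulty spots are argued against by a median of 1.22 (0.77 to 1.79) for the further probes of 11 of the 74 genes.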
